A study of Mus musculus with 24 samples.

How the data were processed

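Total RNA was sequenced from mouse hearts (strain C57BL/6) in 24 libraries, 4 in each of 6 groups: sedentary mice, mice with wheel running for 8 weeks, mice 2 and 8 weeks after transverse aortic constriction (TAC, a surgical narrowing of the aorta that loads the left ventricle with pressure), and a sham-operated group beside each TAC group. Per the labels' protocols, frozen hearts were extracted with Trizol, ribosomal RNA was depleted with RiboZero reagents and libraries were built with an NEB kit. The labels mark the 2-week TAC hearts and their shams as LVH (left ventricular hypertrophy) and the 8-week hearts and their shams as HF (heart failure). The labels give neither sex, age nor time of day at collection, and for the sham groups no time after surgery.

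The deposited table holds estimated counts per gene (the expected counts of Salmon, written as whole numbers), not scaled to a common total and with no gene removed for low counts. Per the submitters' processing notes, FastQC and Salmon were run with the build mm9. The versions of these tools, the transcript annotation, the strand setting and the way transcript estimates were summed to genes are not given in the sources used here. The table has 43432 gene identifiers and 1 further row that names no gene, which was left out. Symbols, gene classes and gene neighbours were taken by identifier from a GENCODE annotation of the later build GRCm38, which named 42462 identifiers and left 970 without a symbol. No coordinates are given, because the builds differ. Genes of the annotation class TEC are unspliced transcribed regions whose class the annotation leaves open until further experiments.

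Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups compared, TMM normalization, a robust quasi-likelihood fit, the two-sided quasi-likelihood F test, and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Each main comparison was fitted on its own 8 libraries: running against sedentary, TAC at 2 weeks against its sham, and TAC at 8 weeks against its sham. No control library is shared between these comparisons. The 3 differences between effects (8-week TAC effect minus 2-week TAC effect, and each TAC effect minus the running effect) and the comparison of the sham groups were tested in the same way as contrasts of group means. Replicate numbers were not used as pairs. Normalized counts (CPM, scaled to a common library total after TMM over all 24 libraries) are given as mean ± SD of 4 libraries.

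Lists of genes were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. They comprise 27 process lists and 14 cell type lists with 846 symbols, of which 26 matched no identifier. Lists with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Beside it, camera with an estimated correlation was run, as was fry. The call of a list rests on the preset correlation unless a sentence says otherwise. Counts of called list members are given over all genes tested and "adjusted over the list alone". Some genes sit in more than 1 list.

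Genes were named by a fixed rule, and not every gene it takes is described. For each main comparison these were the 8 called genes with the largest change in each direction, with a mean CPM of at least 2 and no overlap between the 4 values of one group and the 4 of the other. Up to 2 genes per direction with provisional names (Gm or Rik) followed, then up to 4 members with the smallest p of each list described. Dchs2, Dchs1, Fat4, Yap1, Nppa, Nppb, Myh6, Myh7, Cebpb and Cited4 were always included, and for each difference between effects the 5 genes with the smallest p in each direction. The running genes with the smallest p (Pik3ip1, Tnfaip2, Gdap10, Dyrk2, Fam124b, Cx3cr1), the small RNA Snora73a, and Igf2 were chosen after their values were seen, as were the genes named for the comparison of the sham groups.

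Shares of counts (mitochondrially encoded genes, haemoglobin genes, the 10 most abundant genes, 7SL RNA genes) and total counts were compared with exact two-sided permutation tests over the 70 arrangements of 4 against 4 libraries, adjusted over 21 tests. The smallest p such a test can give is 0.0286. Log2 fold changes of different comparisons were compared with Spearman's rank correlation across genes, and calls shared by comparisons were set beside the number for independent lists.

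The fits were tested on simulated counts drawn from the means and library sizes of these libraries. In the simulation of TAC at 2 weeks (14038 genes) 42% of 50 genes changed 1.5-fold, 72% of those changed 2-fold and 96% of those changed 4-fold were called. In that of TAC at 8 weeks (13417 genes) the shares were 40%, 72% and 98%, and in that of running (13648 genes) 30%, 70% and 92% (edgeR). Only 50 genes were changed at each fold, far fewer than were called in the TAC comparisons. The adjustment is milder where more genes change, so these shares may understate the recovery in the TAC comparisons. Unchanged genes called in the simulations of TAC at 2 weeks, TAC at 8 weeks and running were 4, 5 and 9 by edgeR and 15, 12 and 24 by DESeq2. Camera called 2 of 2 changed lists and 0 of 38 unchanged lists in each simulated comparison. The simulated genes varied independently, so this does not show how often camera calls lists of correlated genes by chance.

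Alternatives changed 1 choice at a time: DESeq2 size factors, no normalization factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a stricter filter, the replicate number as a block, all 24 libraries in 1 fit, a fit without robust estimation, mitochondrially encoded genes left out, and each library left out in turn. A clock score as a term and a term for replicate numbers in the exercise cohort were added after the data were seen. Other splits of the libraries into groups of the same sizes were fitted in the same way: all 35 for 4 against 4, and a seeded draw of 80 or 100 for the others. All p-values measure only the spread between these libraries. Left out were lncExACT1, for which no identifier in the table could be established, and the strand of reads. Positions and strand in the annotation served to find the coding genes that contain or overlap TEC genes.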

Results

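Transcript levels were measured by sequencing of ribosomal-RNA-depleted total RNA in 24 mouse hearts, 4 in each of 6 groups: sedentary, wheel running for 8 weeks, TAC for 2 weeks with its sham group, and TAC for 8 weeks with its sham group. TAC narrows the aorta and loads the left ventricle with pressure, and wheel running is a model of exercise growth of the heart. The title of the series concerns the long noncoding RNA lncExACT1 and the cadherin gene Dchs2 in healthy and diseased cardiac growth. The comparisons address which transcripts differ in each setting and whether the settings differ from each other. The total count per library ranged from 16802939 to 39512101 (median 22845050), and 18646 to 20712 genes had at least 1 count.

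Mitochondrially encoded transcripts took most of the counts and a smaller share in TAC hearts. They held 50.7% to 73.6% of the counts of a library, and mt-Rnr2, the large mitochondrial ribosomal RNA, alone held 39.2% to 55.1%, which left 5949640 to 12932067 counts per library for other genes. The mitochondrial share was 54.3% ± 3.3 (SD, n = 4) 2 weeks after TAC and 62.3% ± 1.96 in the shams (exact two-sided permutation p = 0.0286, adjusted p = 0.0751 over 21 tests). At 8 weeks it was 55.2% ± 2.05 and 64.1% ± 2.51 (exact permutation p = 0.0286, adjusted p = 0.0751). In both comparisons each TAC library lay below each sham library, and 0.0286 is the smallest p such a test can give. Running hearts had 67.5% ± 4.76 and sedentary hearts 65.6% ± 3.16 (exact permutation p = 0.571). Most of the TAC difference lay in the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2. They held 46.9% of counts 2 weeks after TAC and 53.1% in the shams, and 47.4% and 55.2% at 8 weeks (exact permutation p = 0.0286, adjusted p = 0.0751 for each). Whether the depletion of ribosomal RNA differed between the groups was not tested. The 7SL RNA genes, which encode the RNA of the signal recognition particle and share reads among near-identical copies, held 5.92% of counts 8 weeks after TAC and 3.9% in the shams (exact permutation p = 0.0286, adjusted p = 0.0751). At 2 weeks these shares were 6.35% and 4.75% (exact permutation p = 0.0571). Haemoglobin genes held 0.0542% of counts 8 weeks after TAC and 0.0359% in the shams (exact permutation p = 0.0286), but 0.121% and 0.0993% of the counts outside mitochondrial genes (exact permutation p = 0.0857). Total counts did not separate the groups in any main comparison (exact permutation p = 0.914 for running, 0.314 for TAC at 2 weeks, 0.743 for TAC at 8 weeks). The first principal component held 34.4% of the variance of normalized expression, with TAC libraries at 27.4 to 51.5 and the others at -33.2 to -4.76.

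**Figure D1:**
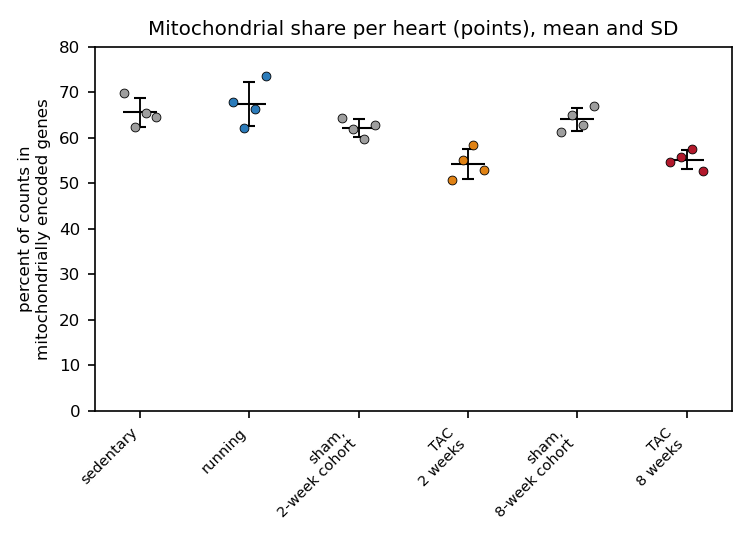
Percent of counts in mitochondrially encoded genes (vertical axis) in each heart (points) of the 6 groups, with group mean (line) and SD (bars). TAC libraries lie lower than their shams at 2 and at 8 weeks, with mean differences of -7.92 and -8.81 percentage points.

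The comparison of TAC at 2 weeks with its sham asks which transcripts change in the hypertrophic stage of pressure overload. Transcripts of Dchs2, an atypical cadherin gene named in the title, rose in TAC hearts, as did those of its relative Dchs1. The natriuretic peptide genes Nppa and Nppb, the slow myosin gene Myh7 and the skeletal actin gene Acta1, which are fetal heart genes that return under load, rose as well. The adult myosin gene Myh6 and the calcium pump gene Atp2a2 fell. Matrix genes and genes of activated fibroblasts rose too.

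Dchs2 (ENSMUSG00000102692) rose 4.48-fold, from 1.05 ± 0.321 CPM in shams to 4.78 ± 0.401 CPM 2 weeks after TAC (log2 fold change 2.16, SE 0.183; edgeR quasi-likelihood test, adjusted p = 3.39e-06). Dchs1 (ENSMUSG00000036862) rose from 16.6 ± 4.16 to 33.0 ± 5.2 CPM (log2 fold change 1.00, SE 0.167; edgeR adjusted p = 0.000833). Fat4, which encodes a binding partner of Dachsous cadherins, rose less (log2 fold change 0.41, edgeR adjusted p = 0.00878), and Fat1 rose with 1.42 (adjusted p = 1.5e-05). Celsr2, another cadherin of this group, fell with -1.18 (edgeR adjusted p = 0.00035). The list of 8 Fat, Dachsous and Celsr cadherin genes held 4 higher and 2 lower genes (4 and 3 adjusted over the list alone) and was not called by camera (median log2 fold change 0.02, adjusted p = 0.153). For the transcriptional regulators Yap1, Cebpb and Cited4 the log2 fold changes were -0.17, -0.59 and -0.33 (edgeR adjusted p = 0.205, 0.176 and 0.283). Nppa rose 19.5-fold to 601 ± 150 CPM (edgeR adjusted p = 2.17e-06), Nppb 6.6-fold (3.98e-06), Myh7 27.4-fold to 825 ± 279 CPM (2.74e-05) and Acta1 8.54-fold to 593 ± 33.8 CPM (3.06e-07). Myh6 fell with a log2 fold change of -1.02 (edgeR adjusted p = 4.57e-05). Each gene described as changed in the TAC comparisons had no overlap between the 4 TAC and the 4 sham values, except where stated. The Myh7 value is uncertain, because reads of Mhrt, a noncoding RNA antisense to it, cannot be told apart without strand.

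Among the larger increases 2 weeks after TAC were those of the matrix and fibroblast genes Cthrc1 (33.1-fold, edgeR adjusted p = 1.5e-05), Col8a2 (19.6-fold, 4.98e-07), Thbs4 (17.8-fold, 3.06e-07), Lox, Ltbp2 and Postn (16.3-fold to 597 ± 158 CPM, 1.51e-06), beside Myh7 and Nppa. Of the 39 matrix genes tested, 38 rose and 0 fell (39 and 0 adjusted over the list alone), with a median log2 fold change of 2.50 (camera, adjusted p = 7.52e-71; adjusted p = 0.0562 with an estimated correlation). Col8a1 (3.09), Col16a1 (2.58) and Sparc (1.94) were among those with the smallest p. Of the 21 activated fibroblast genes 17 rose and 0 fell, over all genes and adjusted over the list alone (median 2.57; camera adjusted p = 1.4e-36, and 0.0256 with an estimated correlation). They included Comp (3.44), Sfrp2 (3.22), Ddah1 (2.57) and Ccn5 (2.35). In the TGF-beta list, a pathway that drives matrix production, 18 of 26 genes rose and 1 fell (19 and 2 adjusted over the list alone; camera adjusted p = 6.97e-09, and 0.132 with an estimated correlation), with Tgfb3 at 1.63 and Tgfbr1 at 0.92. The lncRNA Gm13054 (3.94, edgeR adjusted p = 3.36e-06) and the TEC gene Gm38211 (1.82, 1.13e-05) rose among genes with provisional names.

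**Figure D2:**
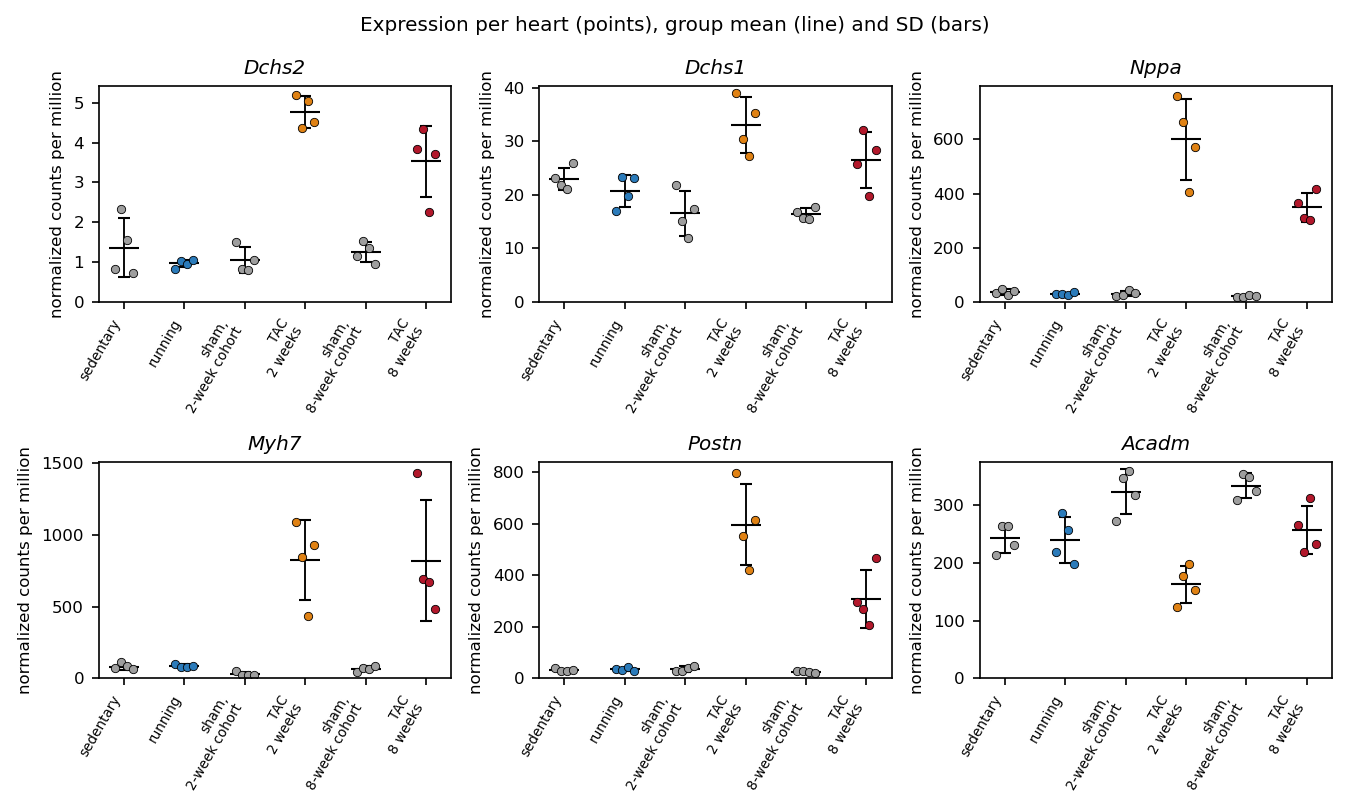
Normalized counts (CPM, vertical axes from 0) of Dchs2, Dchs1, Nppa, Myh7, Postn and Acadm in each heart (points) of the 6 groups, with group mean (line) and SD (bars). Dchs2 lies at 4.78 ± 0.401 and 3.53 ± 0.891 CPM 2 and 8 weeks after TAC and at 0.966 ± 0.0941 CPM after running.

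Energy metabolism genes fell 2 weeks after TAC. Of the 35 fatty acid oxidation genes 31 fell and 0 rose, over all genes and adjusted over the list alone (camera adjusted p = 2.27e-22, and 0.155 with an estimated correlation). Acot2 (-1.31), Crat (-1.05), Etfa (1.99-fold lower) and the lipase gene Pnpla2 (-0.97) had the smallest p. Of the 22 tricarboxylic acid cycle genes 21 fell (22 adjusted over the list alone; median -0.72; camera adjusted p = 5.07e-15, and 0.155 with an estimated correlation), Sdha with -0.93 and Cs with -0.87. Of the 59 nuclear respiratory chain genes 46 fell (52 adjusted over the list alone; median -0.61; camera adjusted p = 1.61e-15, and 0.319 with an estimated correlation), Ndufab1 with -0.73. All 15 mitochondrially encoded genes fell, over all genes and over the list alone, mt-Nd2 with -0.87 and mt-Nd4 with -0.78 (camera adjusted p = 2.82e-08, and 0.243 with an estimated correlation), beside the lower mitochondrial share of counts. Regulators of mitochondrial genes fell in 17 of 20 cases (median -0.59; camera adjusted p = 1.38e-10, and 0.0562 with an estimated correlation), with Ppara at -1.13 and Ppargc1a at -0.99. Branched-chain amino acid and ketone genes fell in 20 of 21 cases (median -0.79; camera adjusted p = 1.13e-17, and 0.106 with an estimated correlation), with Ivd at -1.14 and Bcat2 at -0.78. In the glycolysis list 13 of 24 genes fell and 2 rose (16 and 2 adjusted over the list alone; median -0.37; camera adjusted p = 5.45e-07, and 0.122 with an estimated correlation), with Pygm at -0.94 and Gys1 at -0.73. Phkg1, a subunit of glycogen phosphorylase kinase, fell 5.05-fold (edgeR adjusted p = 1.2e-06).

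Ion channel and contraction genes fell 2 weeks after TAC. Of the 19 potassium and sodium channel genes 16 fell and 0 rose (17 and 0 adjusted over the list alone; median -0.95; camera adjusted p = 3.31e-15, and 0.0294 with an estimated correlation). Kcnv2, a modulating potassium channel subunit, fell 5.02-fold (edgeR adjusted p = 4.05e-06), Kcnj3 with -1.50 and Kcnj5 with -1.10. Of the 16 calcium handling genes 9 fell and 0 rose (median -0.51; camera adjusted p = 0.000111, and 0.157 with an estimated correlation), among them Hrc (-1.34), Atp2a2 (-1.02) and the calcium release channel gene Ryr2 (-0.77). Of the 18 adult sarcomere genes 11 fell (13 adjusted over the list alone; median -0.42; camera adjusted p = 5.69e-05, and 0.155 with an estimated correlation), with Cmya5 at -0.93 and Tnnt2 at -0.71. Other large decreases were those of Ces1d (4.45-fold lower), the water channel gene Aqp4 (4.41-fold lower), the chloride channel gene Clcn1 (4.1-fold lower), Pfkfb1 (4.08-fold lower), Whrn (3.94-fold lower) and Lgals4 (3.92-fold lower), and among provisional names A530016L24Rik (3.49-fold lower) and Gm14327 (-1.56). Fetal cardiomyocyte genes rose in 12 of 16 cases and fell in 1 (13 and 1 adjusted over the list alone; median 1.38; camera adjusted p = 2.85e-17, and 0.106 with an estimated correlation).

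Inflammatory, dividing and stromal cell genes were higher 2 weeks after TAC. Macrophage and monocyte genes rose in 15 of 19 cases and fell in 1 (the same adjusted over the list alone; median 0.75; camera adjusted p = 1.68e-07, and 0.193 with an estimated correlation). Ms4a7 rose 4.94-fold (edgeR adjusted p = 2.47e-06), Ccr2, a receptor of recruited monocytes, with 1.83 and Adgre1 with 1.32. Interferon response genes rose in 20 of 24 cases (22 adjusted over the list alone; median 0.60; camera adjusted p = 1.68e-07, and 0.155 with an estimated correlation), with Irf7 at 0.92. Cell cycle genes rose in 15 of 23 cases and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 6.34e-05, and 0.301 with an estimated correlation). Cdk1 (1.99) and Mcm6 (0.90) rose, whereas Cenpf, a kinetochore gene, fell with -1.38. Resident fibroblast markers rose in 10 of 13 cases and fell in 1 (camera adjusted p = 1.45e-06, and 0.122 with an estimated correlation), with Mfap5 at 2.73 and Tcf21 2.29-fold higher. Smooth muscle and pericyte markers rose in 7 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00457, and 0.155 with an estimated correlation), with Cnn1 at 2.03, Tagln at 1.03 and Abcc9 at -0.89. Immediate early genes rose in 11 of 22 cases (camera adjusted p = 0.0028, and 0.2 with an estimated correlation), with Egr2 at 2.67 and Junb at 0.87. Hippo pathway genes rose in 15 of 30 cases and fell in 2 (17 and 3 adjusted over the list alone; median 0.32; camera adjusted p = 0.0012, and 0.303 with an estimated correlation), with the Yap target Ccn2 at 2.77. Genes tied to physiological growth rose in 2 of 23 cases and fell in 8 (3 and 8 adjusted over the list alone; median -0.14; camera adjusted p = 0.0362, and 0.189 with an estimated correlation), with Igf1 at 1.58 and Tbx5 at -0.95. Without TAC replicate 3 the adjusted p of this list was 0.0554, and without sham replicate 4 it was 0.0522. Endothelial markers rose in 7 of 15 cases and fell in 1 (camera adjusted p = 0.0918). The median and the test differed in sign for the lists of endoplasmic reticulum stress, skeletal muscle and Schwann cell genes, none of which was called.

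In all, 4717 of 14224 genes were called 2 weeks after TAC, 2428 higher and 2289 lower (edgeR), of which 697 were at least 2-fold higher and 351 at least 2-fold lower. Camera called 22 of 39 lists (11 higher, 11 lower), fry 28, and camera with an estimated correlation 2. With scaling to library totals, without normalization factors, the median log2 fold change of all genes was 0.41, and 6995 genes were called higher and 614 lower, so decreases are relative to the median gene.

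The comparison of TAC at 8 weeks with its sham asks which transcripts differ in the stage the labels call heart failure. Dchs2 and Dchs1 were higher at this time too. Acta1, the stress cytokine gene Gdf15, Nppa and matrix genes rose. Genes of fatty acid oxidation and of ion channels fell. A long noncoding RNA that is abundant before birth, H19, fell, and of 255 unspliced TEC genes 96 fell and 1 rose (edgeR; 49 and 3 without normalization factors).

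Dchs2 rose 2.79-fold 8 weeks after TAC, to 3.53 ± 0.891 CPM (2.26 to 4.33 CPM in TAC hearts, 0.958 to 1.53 CPM in shams; log2 fold change 1.48, SE 0.223; edgeR adjusted p = 0.000269). Dchs1 rose from 16.4 ± 1.02 to 26.5 ± 5.21 CPM (0.69, SE 0.124; edgeR adjusted p = 0.00109). Fat1 rose with 0.84 (edgeR adjusted p = 7.29e-05), and Celsr2 fell 2.69-fold (6.58e-05). Fat4 had -0.13 (edgeR adjusted p = 0.397) and Yap1 -0.05 (0.698). The list of Fat, Dachsous and Celsr genes held 3 higher and 3 lower of 7 genes, also over the list alone, and was not called (camera adjusted p = 0.754), with a median of -0.13 against a test direction upward. Nppa rose 16.5-fold to 349 ± 53 CPM (edgeR adjusted p = 5.67e-09) and Myh7 12.2-fold to 819 ± 420 CPM (0.00109), while Myh6 fell with -0.79 (7.1e-05). Nppb was 353 ± 82.1 CPM in TAC hearts and 77.1 ± 70.7 CPM in shams and missed the threshold (log2 fold change 2.19, edgeR adjusted p = 0.0534). Without sham replicate 1 its adjusted p was 0.00455, and DESeq2 gave 0.00739. Cebpb rose (0.77, edgeR adjusted p = 0.00529), but not in a fit of all 24 libraries (0.0852). Cited4 had -0.74 (edgeR adjusted p = 0.0622). Without TAC replicate 1 the adjusted p of Cited4 was 0.0239, without sham replicate 2 it was 0.00979, and DESeq2 gave 0.0353.

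Acta1 rose 26.6-fold to 1217 ± 159 CPM (edgeR adjusted p = 1.84e-06), Gdf15 19.8-fold (2.05e-05), the fibroblast gene Cilp 13.3-fold (0.000147) and Postn 12.2-fold (7.9e-05), with Thbs4 at 3.92 and Ltbp2 at 3.85. Of the 39 matrix genes 36 rose and 0 fell, also over the list alone (median 1.45; camera adjusted p = 1.57e-41, and 0.129 with an estimated correlation), among them Mfap4 (2.37), Bgn (1.64), Sparc (1.26) and Lum (2.27-fold). Of 19 activated fibroblast genes 16 rose (median 1.84; camera adjusted p = 1.41e-21, and 0.0523 with an estimated correlation), among them Ddah1 (1.68), Aspn (1.65) and Sfrp1 (1.43). TGF-beta genes rose in 12 of 26 cases and fell in 3 (13 and 3 adjusted over the list alone; camera adjusted p = 7.46e-05, and 0.294 with an estimated correlation). Fetal cardiomyocyte genes rose in 10 of 16 cases (12 adjusted over the list alone; camera adjusted p = 2.67e-22, and 0.0523 with an estimated correlation), with Ankrd1 at 2.73. Resident fibroblast markers rose in 5 of 13 cases and fell in 1 (median 0.25; camera adjusted p = 0.00217, and 0.23 with an estimated correlation). Pi16 (1.43) and Dcn (0.78) rose and Scara5, a ferritin receptor gene, fell (-1.39).

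Among the larger decreases 8 weeks after TAC were those of Pfkfb1 (5.29-fold lower, edgeR adjusted p = 0.000195), Lgals4 (5.09-fold lower, 0.00136), Cenpf (4.67-fold lower, 1.33e-05), Clcn1, Gal3st3, Gal3st2c and the thioesterase gene Acot1 (3.9-fold lower, 5.77e-06). Fatty acid oxidation genes fell in 30 of 35 cases (31 lower and 1 higher adjusted over the list alone; median -0.49; camera adjusted p = 1.13e-16, and 0.14 with an estimated correlation), with Acaa2 at -0.94, Plin5 at -0.73 and Pnpla2 at -0.67. Regulators of mitochondrial genes fell in 15 of 20 cases (16 adjusted over the list alone; median -0.39; camera adjusted p = 2.71e-06, and 0.0523 with an estimated correlation), with Ppargc1a at -1.44 and Ppara at -0.60. Tricarboxylic acid cycle genes fell in 14 of 22 cases (15 adjusted over the list alone; median -0.32; camera adjusted p = 1.09e-06, and 0.217 with an estimated correlation), Sdha with -0.69. Nuclear respiratory chain genes fell in 15 of 59 cases and rose in 1 (14 and 1 adjusted over the list alone; median -0.11; camera adjusted p = 0.00204, and 0.716 with an estimated correlation). Of the 15 mitochondrially encoded genes 14 fell (median -0.54; camera adjusted p = 8.3e-09, and 0.217 with an estimated correlation), with mt-Nd5 at -0.80 and mt-Nd4 at -0.76, beside the lower mitochondrial share of counts. Branched-chain amino acid and ketone genes fell in 15 of 21 cases and rose in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 1.71e-06, and 0.217 with an estimated correlation). The gene that rose was Bdh1, which encodes a ketone body dehydrogenase (1.06, edgeR adjusted p = 2.13e-05). Glycolysis genes fell in 10 of 24 cases and rose in 4 (camera adjusted p = 0.00796, and 0.217 with an estimated correlation), with Phkg1 at -1.69. Without normalization factors Ppara, Cs, Ndufab1, Akt2, Gstm1 and Sod1 were no longer called at 8 weeks.

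Channel genes fell in 14 of 19 cases 8 weeks after TAC (15 adjusted over the list alone; median -0.73; camera adjusted p = 4.21e-13, and 0.14 with an estimated correlation), with Kcnv2 at -1.78, Kcnh2 at -1.37, Kcnd2 at -1.36 and Kcnj3 at -1.23. Calcium handling genes fell in 6 of 16 cases and rose in 3 (8 and 3 adjusted over the list alone; median -0.32; camera adjusted p = 0.0153, and 0.158 with an estimated correlation), with Hrc at -0.92, Ryr2 at -0.88 and Cacna1c at -0.82. The sarcomere list was not called (6 of 18 lower, 3 higher; median -0.07; camera adjusted p = 0.231), nor was the Hippo list (7 of 30 higher, 5 lower; camera adjusted p = 0.105), in which Amot rose with 1.32. Genes tied to physiological growth fell in 11 of 23 cases and rose in 2 (12 and 2 adjusted over the list alone; median -0.32; camera adjusted p = 0.00732, and 0.217 with an estimated correlation), with Igf1 at 0.96 and the insulin signalling kinase gene Akt2 at -0.53. Oxidative stress genes rose in 10 of 22 cases and fell in 3 (13 and 3 adjusted over the list alone; median 0.39; camera adjusted p = 0.00355, and 0.217 with an estimated correlation), with Hmox1 2.22-fold higher, Gpx1 at 0.91, Gstm1 at -0.56 and Sod1 at -0.52. Macrophage genes rose in 14 of 19 cases (15 adjusted over the list alone; median 0.80; camera adjusted p = 1.72e-07, and 0.217 with an estimated correlation), with Adgre1 2.19-fold higher, C1qb at 0.96 and Mrc1 at 0.67. Interferon genes rose in 17 of 24 cases (18 adjusted over the list alone; median 0.74; camera adjusted p = 2.38e-07, and 0.193 with an estimated correlation), with Ifi27l2a at 1.31 and Ifit3 2.28-fold higher. Cell cycle genes rose in 14 of 23 cases and fell in 1 (17 and 1 adjusted over the list alone; median 0.82; camera adjusted p = 7.46e-05, and 0.217 with an estimated correlation), with Top2a at 1.36 and Mki67 at 0.92. Of 15 endothelial markers 0 were called by edgeR, also over the list alone (camera adjusted p = 0.753). The median and the test differed in sign for the clock, angiogenesis, pericyte and mesothelial lists, none of which was called.

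In all, 4032 of 13621 genes were called 8 weeks after TAC, 2032 higher and 2000 lower (edgeR), 422 of them at least 2-fold higher and 338 at least 2-fold lower. Camera called 20 of 37 lists (9 higher, 11 lower), fry 21, and camera with an estimated correlation 0. Without normalization factors the median log2 fold change of all genes was 0.34, and 6075 genes were called higher and 568 lower.

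**Figure D3:**
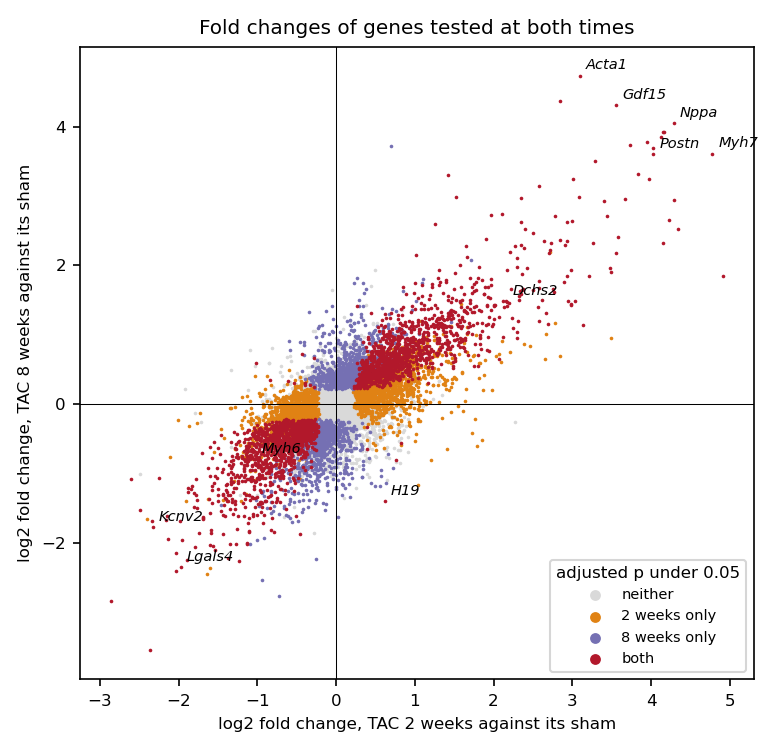
Log2 fold change of each gene tested in both TAC comparisons, at 2 weeks (horizontal axis) and at 8 weeks (vertical axis), each against its own sham group. Colours mark genes called at both times, at 1 time or at neither, and 1191 genes were higher and 1155 lower at both times.

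Most TAC changes had the same direction at 2 and 8 weeks. Of 13542 genes tested in both comparisons 1191 were called higher at both times and 1155 lower at both, where independent lists would share 347 and 331. Opposite calls numbered 5 and 10, with 341 and 336 for independent lists. Log2 fold changes correlated across genes (Spearman's rho 0.643, Pearson's r 0.731), and 71.8% had the same sign, although genes are not independent replicates.

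The difference between the TAC effects at 8 and 2 weeks tests which transcripts responded differently at the 2 times. Each time had its own cohort and its own shams, and the sham groups differed from each other in 497 genes. Time after TAC and cohort cannot be told apart here. H19, an imprinted lncRNA, rose at 2 weeks (0.62, edgeR adjusted p = 0.00248) and fell at 8 weeks (-1.40, 5.76e-05), and the difference was called (-2.01, 0.000245). H19 was also higher in shams of the 8-week cohort than in those of the 2-week cohort, so part of this difference lies in the shams. Bdh1 (2.16-fold difference, edgeR adjusted p = 0.00243), the cytochrome oxidase translation gene Taco1 (0.85, 0.0133), Acta1 (1.65, 0.0148), the coenzyme Q gene Coq5 (0.69, 0.0148) and Narf (0.70, 0.0148) had the more positive effect at 8 weeks. The procollagen protease gene Bmp1 (-0.86, edgeR adjusted p = 0.00876), Pitpnm1 (-0.90, 0.0148), the guanylate cyclase gene Gucy1a1 (-0.72, 0.0172) and Arhgap18 (-1.37, 0.0172) had the more negative effect. These 10 genes kept their calls without each of the 16 libraries, but Acta1 (0.0568), Coq5 (0.0676) and Narf (0.0781) were not called without normalization factors, nor Acta1 in a fit of all 24 libraries (0.12). The imprinted growth factor gene Igf2 differed too (-1.10, edgeR adjusted p = 0.0219), but not without TAC replicate 4 at 8 weeks (0.0523) or sham replicate 2 at 2 weeks (0.0549). For Dchs2 the difference was -0.68 (edgeR adjusted p = 0.227), for Dchs1 -0.30 (0.494), for Nppa -0.23 (0.722) and for Myh7 -1.16 (0.262). For Fat4 it was -0.53 (edgeR adjusted p = 0.0781; 0.0159 without sham replicate 1 at 2 weeks, 0.034 by DESeq2) and for Cebpb 1.37 (0.0869; 0.0311 without the same library, 0.00933 by DESeq2).

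Matrix genes rose less and metabolic genes fell less at 8 than at 2 weeks, as lists. The effect on the 39 matrix genes was lower at 8 weeks in 38 (median difference -0.79; camera adjusted p = 9.72e-17, and 0.231 with an estimated correlation), with 5 genes called over all genes and 22 adjusted over the list alone. For the 59 nuclear respiratory chain genes it was more positive in 58 (median 0.49; camera adjusted p = 1.73e-18, and 0.285 with an estimated correlation), with 1 gene called and 33 over the list alone. The median difference was 0.46 for fatty acid oxidation genes (camera adjusted p = 4.28e-11, and 0.282 with an estimated correlation), 0.41 for branched-chain amino acid and ketone genes (1.7e-12, and 0.138), 0.41 for tricarboxylic acid cycle genes (3.58e-11, and 0.231) and 0.32 for sarcomere genes (6.54e-06, and 0.138). The 8 Fat, Dachsous and Celsr genes had lower effects at 8 weeks (median -0.38; camera adjusted p = 0.00871, and 0.285 with an estimated correlation), with 0 called over all genes by edgeR and 2 over the list alone. Camera called 20 of 39 lists, fry 11, and camera with an estimated correlation 0.

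In all, 196 of 14463 genes differed between the TAC effects, 135 more positive and 61 more negative at 8 weeks (edgeR; 2764 at unadjusted p under 0.05), and single libraries decided this count. It was 48, 384, 66 and 48 without TAC replicates 1 to 4 of the 8-week cohort and 62, 114, 34 and 40 without its sham replicates. It was 46, 67, 488 and 52 without TAC replicates 1 to 4 of the 2-week cohort and 654, 22, 41 and 159 without its sham replicates. DESeq2 called 626 genes, edgeR without normalization factors 30, and edgeR with a score of the clock genes as a term, chosen after the data were seen, 1. Whether the clock term lowered the fold changes or only raised their error was not examined, so the last count does not decide on the clock.

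The comparison of running with sedentary hearts asks which transcripts change in exercise-induced growth. No gene passed the threshold in the main fit. Pik3ip1, a negative regulator of PI3-kinase signalling, was the gene nearest to it. With the replicate number as a block some genes passed, as given with the other settings below. Mitochondrially encoded genes leaned upward as a list and matrix genes downward, by camera at its preset correlation only. Clock genes, which pace daily cycles of transcription, were called upward in the same way, although members moved in both directions.

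Of 13824 genes, 0 were called by edgeR (311 higher and 354 lower at unadjusted p under 0.05), 9 by DESeq2 (4 higher, 5 lower; it called 24 unchanged genes in simulated data, and edgeR 9), 2 without a filter on low counts and 3 without running replicate 4. Pik3ip1 was 19.8 ± 2.98 CPM in running and 10.8 ± 1.33 CPM in sedentary hearts (log2 fold change 0.87, SE 0.125; edgeR adjusted p = 0.126, DESeq2 adjusted p = 2.64e-05, and 0.0232 by edgeR without running replicate 4), with no overlap of the groups. The genes with the next smallest p were Tnfaip2 (-0.56, edgeR adjusted p = 0.386, DESeq2 0.00422), Gdap10 (0.95, 0.558, DESeq2 0.00133), Dyrk2 (-0.54, 0.558), Fam124b (-3.04, 0.558, DESeq2 0.00169) and the macrophage receptor gene Cx3cr1 (-1.52, 0.558, DESeq2 0.014). Dchs2 was 0.966 ± 0.0941 CPM in running and 1.36 ± 0.743 CPM in sedentary hearts (log2 fold change -0.48, edgeR adjusted p = 1). Its value was -0.08 without sedentary replicate 2, the heart with 2.33 CPM, and -0.69 without sedentary replicate 1. The values for Dchs1, Nppa, Nppb, Myh6, Myh7, Cebpb and Cited4 were -0.14, -0.27, -0.14, -0.07, 0.05, 0.23 and -0.50, each with overlapping groups and an edgeR adjusted p of 1. Leaving out single libraries turned the sign for Nppb (-0.48 to 0.08), Myh7 (-0.05 to 0.22) and Cebpb (-0.08 to 0.48) and gave -0.76 to -0.07 for Cited4.

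Camera called 3 of 36 lists after running, and 0 with an estimated correlation or by fry. It called 7, 10, 7 and 5 without running replicates 1 to 4 and 9 and 5 without sedentary replicates 1 and 2. All 15 mitochondrially encoded genes had positive values (median 0.18; camera adjusted p = 2.91e-09, and 0.329 with an estimated correlation), with 0 called over all genes (edgeR) and 2 adjusted over the list alone. The values were 0.32 for mt-Nd2, 0.29 for mt-Nd4l, 0.23 for mt-Cytb and 0.40 for mt-Atp8. Of 39 matrix genes 28 had negative values (median -0.16; camera adjusted p = 4.32e-05, and 0.996 with an estimated correlation), with 0 called over all genes or over the list alone by edgeR and values of -0.49 for Fbn1, -0.41 for Col1a1, -0.38 for Loxl1 and -0.34 for Col6a3. The 21 clock genes (median 0.66; camera adjusted p = 7.97e-05, and 0.329 with an estimated correlation) had 9 higher and 5 lower adjusted over the list alone and 0 over all genes by edgeR. Tef had 0.99, Arntl -2.57 (0.358 to 2.78 against 4 to 10.9 CPM), Npas2 -1.64 and Clock -0.41 (edgeR adjusted p = 0.858, 0.858, 0.719 and 0.858; DESeq2 0.00784 for Tef and 0.0313 for Npas2). The median and the test differed in sign for the lists of potassium channel, sarcomere, heat shock, macrophage, respiratory chain, cell cycle and atrial genes, none of which was called.

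**Figure D4:**
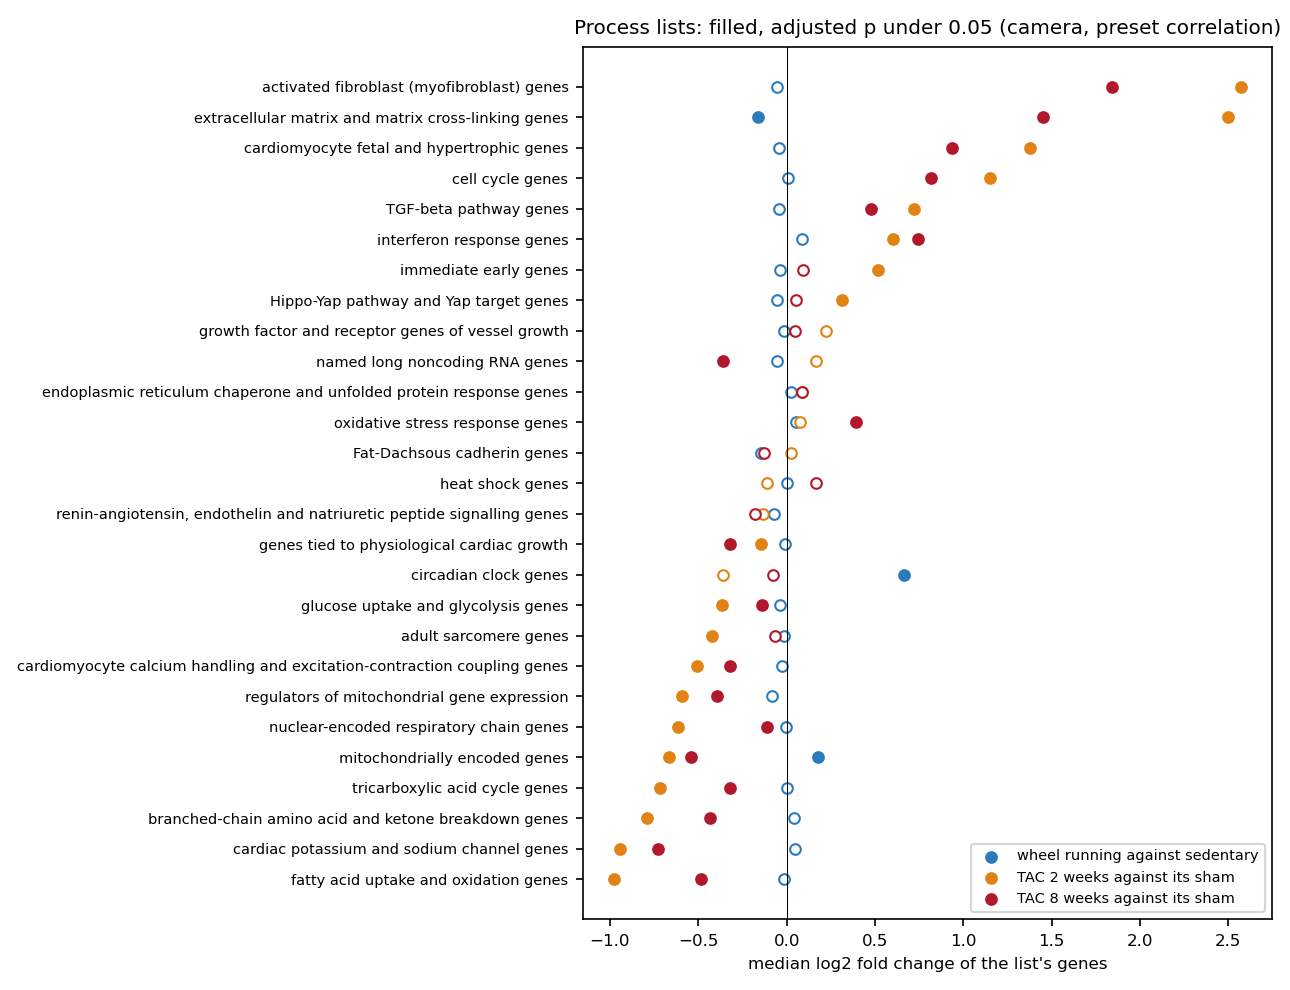
Median log2 fold change (horizontal axis) of the tested genes of each process list (vertical axis) for running, TAC at 2 weeks and TAC at 8 weeks, each against its controls. Filled points mark lists that camera called at the preset correlation, 3 of them for running.

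The differences between the TAC and running effects test whether a gene responds differently to TAC against sham than to running against sedentary. The interventions also differ in cohort, in control (sham-operated or sedentary) and, for TAC at 2 weeks, in duration. These cannot be told apart from pressure overload and exercise themselves. Dchs2 differed from running at 2 weeks (2.64, edgeR adjusted p = 0.000106) and at 8 weeks (1.97, 0.00444), as did Dchs1 (2.2-fold, 0.00118; 1.79-fold, 0.00402). Nppa (4.56, edgeR adjusted p = 4.19e-07) and Myh7 (4.72, 7.52e-06) were higher and Myh6 lower (-0.96, 6.39e-05) in the 2-week difference. At 8 weeks the differences were 4.33 for Nppa (edgeR adjusted p = 2.75e-08), 3.57 for Myh7 (0.000221) and -0.71 for Myh6 (0.0012). The Myh6 differences were not called without normalization factors. The smallest p at 2 weeks belonged to Thbs4 (4.37, edgeR adjusted p = 5.3e-10), the matrix genes Svep1 (2.27), Igfbp7 (1.79) and Col16a1 (2.74), and Dio2, which encodes a thyroid hormone deiodinase (3.75). In the other direction were the muscle ubiquitin ligase gene Asb15 (-1.45, edgeR adjusted p = 4.19e-07), Phkg1 (-2.32), Kcnv2 (-2.60), the desmosome gene Dsg2 (-1.58) and Wnk2 (-1.59). At 8 weeks they belonged to Nppa, Igfbp7 (1.67, edgeR adjusted p = 2.5e-07), Svep1 (2.26), Adcy7 (1.88) and Aqp8 (12.1-fold), and to the adrenergic receptor gene Adra1a (-1.59, 4.12e-06), Asb15 (-1.19), Car14 (-0.91) and Phkg1 (-1.66).

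Matrix genes were higher after TAC than after running in 37 of 39 cases at 2 weeks (38 adjusted over the list alone; camera adjusted p = 9.11e-86, and 0.00371 with an estimated correlation) and in 35 of 39 at 8 weeks (36 over the list alone; 1.62e-56, and 0.0093). Activated fibroblast genes (camera adjusted p = 0.000352 and 0.00394 with an estimated correlation at 2 and 8 weeks) and fetal cardiomyocyte genes (0.0489 and 0.0093) kept their calls too. Mitochondrially encoded genes were lower in 15 of 15 cases at 2 weeks (camera adjusted p = 2.13e-15, and 0.0542 with an estimated correlation) and in 13 of 15 at 8 weeks (15 over the list alone; 9.43e-17, and 0.0467), beside the lower mitochondrial share of counts after TAC. Fatty acid oxidation genes were lower in 30 of 35 cases at 2 weeks (camera adjusted p = 3.68e-20, and 0.119 with an estimated correlation) and in 12 at 8 weeks (20 over the list alone; 3.59e-11, and 0.299). The list of genes tied to physiological growth was not called at 2 weeks (median -0.05; camera adjusted p = 0.285) or at 8 weeks (median -0.14; 0.0719), nor was the list of Fat, Dachsous, Celsr and related genes (0.0699 and 0.746), although Dchs2 and Dchs1 differed.

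In all, 2807 of 14729 genes differed between TAC at 2 weeks and running (1399 higher, 1408 lower; edgeR) and 1581 of 14252 between TAC at 8 weeks and running (818 higher, 763 lower). Without normalization factors these splits were 4506 higher and 214 lower, and 3028 and 170. Log2 fold changes of running correlated little with those of TAC across genes (Spearman's rho -0.0716 at 2 weeks over 13625 genes, 0.0672 at 8 weeks over 13380). Without running replicate 2 the former was 0.0415 and without sedentary replicate 1 it was 0.0321. No gene was called by edgeR in both running and a TAC comparison, since running called 0.

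The sham groups of both cohorts, sham hearts beside the 8-week and beside the 2-week TAC hearts, differed from each other. Cohort, time after surgery and any difference in age or collection cannot be told apart here. Ppargc1a, a regulator of mitochondrial biogenesis, was higher in the 8-week cohort (edgeR adjusted p = 0.00013), as were Vegfa (0.81, 0.00788), Irs1 (0.70, 0.00614) and H19 (0.82, 0.0116). Arntl (3.50, edgeR adjusted p = 0.0167), Npas2 (2.05, 0.00862) and Clock (0.67, 0.0107), which form the activating arm of the clock, were higher and Hlf lower (-1.51, 0.00349). Arntl was not called without sham replicate 3 of the 8-week cohort (0.0541) or sham replicate 2 of the 2-week cohort (0.0602). Lum (-0.84, edgeR adjusted p = 0.00974), Col8a1 (-0.76, 0.00349), the macrophage gene Siglec1 (-1.23, 0.00524) and the interferon gene Ifi27l2a (-1.28, 0.00702) were lower. As lists, immediate early genes were higher (median 0.85; 4 of 21 called, 9 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.44e-07, and 0.365 with an estimated correlation), and macrophage genes (median -0.57; 5 of 19 lower, 8 over the list alone; 9.03e-08, and 0.365) and interferon genes (median -0.44; 4 of 22 lower, 8 over the list alone; 1.45e-07, and 0.239) were lower. Clock genes had 4 higher and 5 lower of 21 (4 and 8 adjusted over the list alone; camera adjusted p = 0.00668, and 0.184 with an estimated correlation). In all, 497 of 13656 genes were called, 301 higher and 196 lower in the 8-week cohort (edgeR; DESeq2 876, edgeR without a filter on low counts 768, and without normalization factors 363, 111 higher and 252 lower). With the clock score as a term, a setting added after the data were seen, 0 genes were called (edgeR, 620 at unadjusted p under 0.05). Clock genes themselves separated the sham groups, so this term can end calls whatever their cause. The count does not decide whether the clock accounts for the other differences. Without sham replicates 1, 3 and 4 of the 8-week cohort the count was 219, 57 and 275, and without sham replicates 1 to 4 of the 2-week cohort it was 1081, 92, 198 and 254.

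With normalization factors, lncRNA genes were called lower more often than higher after TAC, while 59 of 105 small and other noncoding genes were higher at 8 weeks (edgeR). At 8 weeks H19 and the nuclear RNAs Malat1 (-0.61, edgeR adjusted p = 0.000489) and Kcnq1ot1 (-1.03, 0.000313) fell. The value of Kcnq1ot1 is uncertain, because it overlaps Kcnq1 on the other strand. Mhrt, antisense to Myh7, had -0.98 at 2 weeks (edgeR adjusted p = 0.00161) and -1.05 at 8 weeks (0.000556), uncertain for the same reason as Myh7. Dnm3os (3.02-fold higher, edgeR adjusted p = 7.7e-05) and the imprinted Rian (1.09, 0.000629) rose at 2 weeks. The list of named lncRNAs was called at 8 weeks (7 of 20 lower, 1 higher; 8 and 3 adjusted over the list alone; median -0.36; camera adjusted p = 0.00322, and 0.217 with an estimated correlation) and not at 2 weeks (6 higher, 1 lower; 0.276). In the difference between the times all 20 values were negative (median -0.43; camera adjusted p = 8.06e-08, and 0.138 with an estimated correlation). Of all lncRNA genes, 27 rose and 93 fell of 662 tested at 2 weeks, and 26 rose and 137 fell of 555 at 8 weeks (edgeR). Without normalization factors 138 were higher and 37 lower at 2 weeks, and 64 higher and 64 lower at 8 weeks, so the direction of this class depended on the scaling. After running, 0 of 654 were called by edgeR (36 at unadjusted p under 0.05, and 1 by DESeq2). The lncRNAs Gm10435 (-2.10, edgeR adjusted p = 0.0051) and Gm15943 (3.99-fold lower, 0.0293) fell at 8 weeks among genes with provisional names, and the lncRNA Gm20628 (2.17-fold) and the small RNA Gm25835 (2.2-fold) rose. Gm15943 was not called without any of the 4 TAC replicates (0.052 to 0.0747) or without sham replicate 4 (0.0693).

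**Figure D5:**
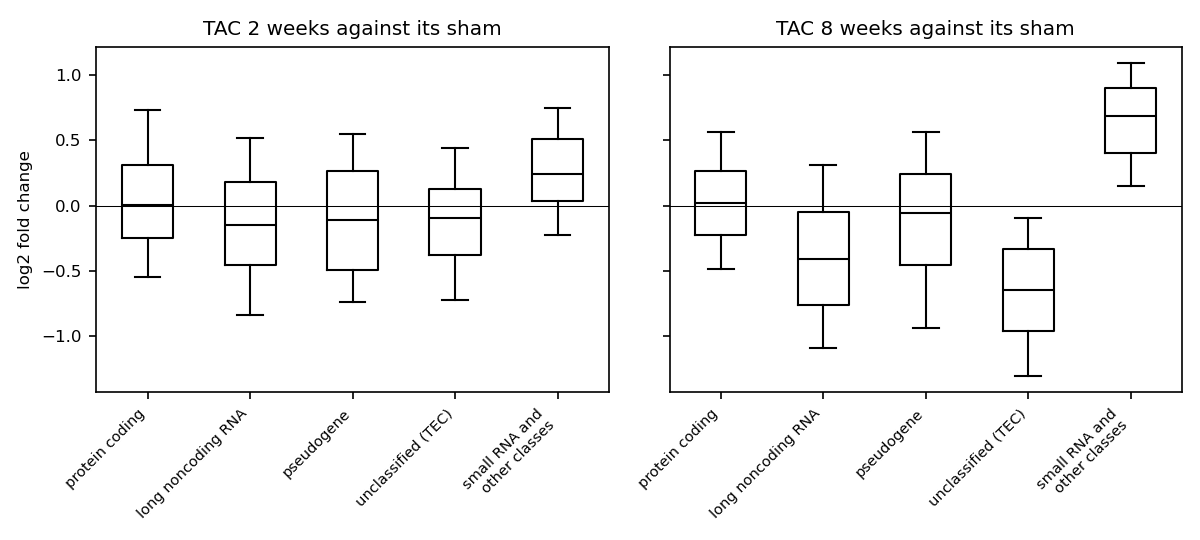
Log2 fold changes (vertical axis) of the genes of each annotation class 2 weeks (left) and 8 weeks (right) after TAC, as medians (line), middle 50% (box) and 10th to 90th percentiles (whiskers). At 8 weeks the median is -0.64 for TEC genes and 0.69 for small RNA and other classes.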

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

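The tests of immediate early genes and of fatty acid oxidation against sarcomere genes, and the counts over other splits of the samples, were chosen only after the results they concern were seen, and the reading of the tests with the mitochondrial percent, of scaling at 8 weeks and of the splits of differences or for a count of 0 was changed after their values were seen.

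Replicates 1 and 4 of the running and sedentary groups together differed from replicates 2 and 3 in 634 of 13824 genes (edgeR, 414 higher, 220 lower). This stands against 0 between running and sedentary hearts and at most 1 in any other split. In the labels, replicates 1 and 4 have library numbers 1, 2, 7 and 8, and replicates 2 and 3 have 3 to 6. The split points to a structure of the samples that goes with the library order, whose meaning the labels do not give. The phase of the clock is not decided. With the first component of the clock genes as a term 873 genes were called, 623 of them shared with the 634. In this split 0 of 21 clock genes were called (median log2 fold change -0.02). Each side mixes running and sedentary hearts, whose Arntl values did not overlap (-2.57 after running), which adds to the error of such genes. Whether the first component follows running or this split was not examined. Mean log2 CPM over the clock list was 3.58 and 3.414 in sedentary replicates 1 and 4 and 2.942 and 2.949 in 2 and 3. In running hearts it was 3.691 and 3.514 against 3.604 and 3.647. The share of mitochondrial reads (69.0% ± 3.79 in replicates 1 and 4, 64.1% ± 2.14 in 2 and 3) cannot be told apart from the split: with it as a term 49 genes were called (44 shared), while the median absolute log2 fold change of the 634 genes went from 0.54 to 0.50 and its SE from 0.116 to 0.151, so the larger error ended most calls. Handling or collection of the hearts could give the pattern and stays open as a hypothesis, since 47.6% of immediate early genes were called against 4.59% of all genes (10 of 21 higher), among them Socs3 (1.37), Btg2 (1.07) and Jun (0.63), chosen after their values were seen, but metabolic genes differed too, with 11 of 35 fatty acid oxidation genes lower and Ppargc1a higher (0.97, adjusted p = 0.00206). Over 629 of the called genes the log2 fold changes correlated with those between the sham groups (Pearson's r 0.647, genes not being independent replicates), and apart from the clock no biological explanation was tested.

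TEC genes, unspliced transcribed regions of open class, were lower 8 weeks after TAC, 96 of 255 called lower and 1 higher (edgeR; median log2 fold change -0.64; 49 lower and 3 higher without normalization factors). The genes that contain them do not account for it, since the median difference between a TEC gene and its coding host was -0.62 over 182 hosts (-0.71 to -0.56 leaving out single libraries), with a host median of -0.09. Low expression does not account for it either: 92.9% of TEC genes had negative values against 42.4% of coding genes matched for level, a difference of 50.6 percentage points (45.7 to 51.4). Reads from unspliced coding transcripts as the cause in all TEC genes are argued against by those that overlap no coding gene (36 genes, median -0.71). They were no higher than those inside one (219 genes, median -0.62, difference 0.0903, 0.0408 to 0.181). For the 219 genes inside coding genes such reads are not excluded, because another cause could lower both kinds alike. A lower share of nuclear RNA in the extracts stays open and was not tested, as does a lower output of such regions, which could be a biological effect of TAC.

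Fatty acid oxidation genes fell at both times after TAC, 31 and 30 of 35 genes. A lower share of cardiomyocytes as the whole cause was set against the sarcomere genes, which come from the same cells. The fatty acid oxidation median minus the sarcomere median was -0.55 at 2 weeks (-0.61 to -0.50 leaving out single libraries) and -0.42 at 8 weeks (-0.46 to -0.34). This gap goes against that cause only if sarcomere transcripts per cell stayed the same, which was not tested. Sarcomere genes were called in both directions at 8 weeks, so the gap does not decide. The scaling of the libraries as the whole cause is argued against at 2 weeks, where 26 of the 31 genes were still called lower without normalization factors (list median -0.58, median of all genes 0.41). At 8 weeks 12 of the 30 genes were still called lower (list median -0.16, median of all genes 0.34), but this setting moves all genes alike, so the lost calls follow from the shift and do not decide on scaling, and the list lay below the median gene either way. The hypothesis that cardiomyocytes lowered these transcripts per cell at 2 weeks could be tested by counts of cell types, which were not used here.

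Other splits of the same 8 libraries were counted for each comparison (35 splits, the real one included). For TAC at 2 weeks 1 split, the real one, reached 4717 genes (highest other 0). For TAC at 8 weeks 1 reached 4032 (highest other 1), and for the sham groups 1 reached 497 (highest other 1). No other split came near these counts, but 1 of 35 is the smallest share these splits can give. The others also mixed hearts of both real groups, which adds any real difference to the error. The splits alone therefore do not exclude chance. For running the real count was 0, which all 35 splits reach whatever the data (highest other 634), so this count says nothing about chance. Among lncRNA genes 1 split reached 120 at 2 weeks (highest other 0), 1 reached 163 at 8 weeks (highest other 0), and for running the count of 0 is again reached by all 35 whatever the data (highest other 20). For lists called by camera, 35 splits reached the 3 of running (highest other 21), 9 reached the 22 of TAC at 2 weeks (highest other 25) and 4 reached the 20 of TAC at 8 weeks (highest other 20), so chance cannot be excluded for the number of lists. Over 80 splits that regrouped 2 comparisons at once, 1 reached the 196 genes that differ between the TAC times (highest other 1), and 6 reached the 20 lists (highest other 22). For TAC at 2 weeks against running 3 of 80 splits reached 2807 genes (highest other 4926), and for TAC at 8 weeks against running 2 reached 1581 (highest other 2390). These larger splits were those that kept the TAC hearts and the running hearts in their groups and regrouped controls alone. All others of these differences mixed TAC with running hearts, which adds the difference between such hearts to the error. For the difference between the TAC times, all other splits mixed TAC hearts of both times, with the same consequence. For these differences the splits therefore do not decide whether chance can be excluded. For genes called in the same direction at both TAC times, 1 of 100 splits reached 2346 (highest other 0). The other splits paired here called 0 genes at 2 weeks, so they could share none whatever the data. This count does not decide on chance either.

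The effects of TAC at 8 and 2 weeks differed by the test of the difference in 196 genes. Genes with the more positive effect at 8 weeks included Bdh1 (1.1), Taco1 (0.85), Coq5 (0.69), Narf (0.70), Acta1 (1.65), Dlat (0.55), Dlst (0.47), Ndufa10 (0.59), Dgat2 (0.90), Oxct1 (0.73), Cmya5 (0.55), the catalase gene Cat (0.57), Gsta4 (0.88), the sodium channel gene Scn4b (1.56) and Amot (0.88). Those with the more negative effect included Col3a1 (-1.55), Col18a1 (-1.09), Col6a1 (-0.86), the elastin gene Eln (-1.99), Bmp1 (-0.86), H19 (-2.01), Igf2 (-1.10), Pitpnm1 (-0.90), Gucy1a1 (-0.72), Arhgap18 (-1.37), Ms4a7 (-1.34) and Steap4 (-0.67). The calls of Dlat, Dlst, Ndufa10, Dgat2, Cmya5, Gsta4, Scn4b, Amot, Col3a1, Col18a1, Col6a1, Eln, Ms4a7 and Steap4 were each lost without at least 6 of the 16 libraries when these were left out in turn. Those of Igf2 (without TAC replicate 4 of the 8-week cohort, adjusted p = 0.0523, or sham replicate 2 of the 2-week cohort, 0.0549), Oxct1 (without sham replicate 4 of the 8-week cohort, 0.0501, or sham replicate 2 of the 2-week cohort, 0.0549) and Cat (without the latter, 0.0549) were lost without 1 or 2 (edgeR).

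Tested were 447 group values of named genes, total counts and shares of counts. Of these, 25 (5.59%) had a single heart far from the other 3, all of them values of named genes, and chance flags about 1 in 20 groups. Of the 25, 6 concerned sham replicate 1 of the 2-week cohort: Fat4 33.6 CPM (others 23.9 to 25.3), Myh7 50.2 (20.8 to 25.6), Cited4 4.19 (2.18 to 2.51), Lgals4 12.8 (9.1 to 9.52), Mhrt 12.5 (6.65 to 7.59) and Adgre1 5.62 (9.49 to 9.74). In TAC hearts of this cohort the values were Acot2 8.43 CPM (12.9 to 13.8), Ccr2 13.2 (9.19 to 9.6) and Adgre1 26.8 (19.3 to 20) in replicate 1, Herpud1 48.9 (29.7 to 32.3) in replicate 2 and Tgfbr1 24.7 (28.9 to 29.2) in replicate 3, with Gm13054 0.662 (0.251 to 0.281) in sham replicate 3 and Usp2 34.5 (39.8 to 40.4) in sham replicate 4. In TAC hearts of the 8-week cohort they were Gm10435 6.03 CPM (3.17 to 3.64), mt-Nd4 5450 (4361 to 4486) and Phkg1 2.71 (2.1 to 2.18) in replicate 2, Aspn 34.6 (41.1 to 42.3) and Snora73a 47.8 (40.8 to 41.9) in replicate 3 and Uchl1 4.02 (4.23 to 4.27) in replicate 4. In its shams they were Ankrd1 252 CPM (164 to 175), Kcnd2 15.5 (18.4 to 18.8) and Pi16 22.2 (15.9 to 16.5) in replicate 1 and Cacna1c 334 (267 to 276) in replicate 4. Nppb was 27.1 CPM in sedentary replicate 1 (49.9 to 54.4) and Dyrk2 5.97 CPM in running replicate 4 (6.97 to 7.17).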

How the results depend on the processing

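The settings with the clock score as a term and with replicates 1 and 4 against 2 and 3 as a term were added after the data were seen. For 281 values of named genes 4462 refits were compared with the main fit. Of these, 4224 stayed on the same side of the threshold, 206 lost the call, 32 gained one and 0 reversed the direction of a called value. The direction of values that were not called was not compared in these counts, and some of them turned sign, as given above for running. Small changes were found less often: in data simulated at the depth of these libraries, which was not varied, the edgeR test found 30%, 42% and 40% of 1.5-fold changes for running, TAC at 2 weeks and TAC at 8 weeks, and 70%, 72% and 72% of 2-fold changes. Far fewer genes were changed in the simulations than were called after TAC, so the shares for TAC may be understated.

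Without normalization factors 7609 genes were called for TAC at 2 weeks, 6643 for TAC at 8 weeks, 30 for the difference between the TAC times, 4720 and 3198 for TAC against running at 2 and 8 weeks, and 4737 in the same direction at both TAC times; the median of all genes moved with this setting by its construction. In the sham groups it called 363 genes, 111 higher and 252 lower, against 301 and 196 with factors. DESeq2 called 9 genes for running (1 of them a lncRNA gene), 876 between the sham groups and 626 for the difference between the TAC times, and 6 and 2 genes in opposite directions in running and TAC at 2 and 8 weeks. With no filter on low counts 2 genes were called for running, 768 between the sham groups, and 2 and 1 in opposite directions in running and TAC at 2 and 8 weeks. The cause was not tested for DESeq2 or the filter. With the clock score as a term 0 genes were called between the sham groups (edgeR) and 1 for the difference between the TAC times. Clock genes themselves differed between the cohorts, so neither count decides on the clock as a cause. With replicates 1 and 4 against 2 and 3 as a term 1 gene was called for running. Other settings gave 4451 to 5359 genes for TAC at 2 weeks and 3571 to 4139 for TAC at 8 weeks.

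With the number shared by replicates as a replicate block, 47 genes (25 higher, 22 lower) were called for running, 3 of them lncRNA genes, and 656 for the difference between the TAC times. Running then shared 2 genes in the same and 27 in the opposite direction with TAC at 2 weeks and 3 and 12 with TAC at 8 weeks. For running the 4 correlations between hearts of the same number, after removal of group means, were all positive (0.343, 0.217, 0.0843 and 0.0386), and replicates 1 and 4 against 2 and 3 differed in 634 genes, so the numbers carried some structure shared by running and sedentary hearts. Running replicates 3 and 4 correlated better with another number (0.166 and 0.111). The correlations were -0.0248 to 0.176 for TAC at 2 weeks and -0.174 to 0.0811 at 8 weeks. The numbers were not taken as pairs, since no comparison had all 4 over 0.1. In the exercise cohort hearts of the same number had adjacent library numbers in the labels (1 and 2, 3 and 4, 5 and 6, 7 and 8). The labels do not say what adjacent libraries share, so a pairing stays possible there. The replicate block changed no other count by over 1.5 times.

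Camera with an estimated correlation called 0 lists for running, 2 for TAC at 2 weeks, 0 for TAC at 8 weeks and 0 for the difference between the TAC times, and fry 0 for running and 11 for that difference. Of 65 called lists 2 kept the call with an estimated correlation, 50 with fry and 65 with DESeq2 size factors. Against the total without mitochondrial genes, the TAC differences in the share of the 10 most abundant genes were -1.45 and -0.158 percentage points at 2 and 8 weeks (exact permutation p = 0.0857 and 0.8) and that of haemoglobin genes 0.0217 at 8 weeks (0.0857).

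Without single replicates the number of called genes was 0 to 3 for running, 3923 to 4575 for TAC at 2 weeks, 2984 to 4204 for TAC at 8 weeks, 57 to 1081 between the sham groups, 22 to 654 for the difference between the TAC times, 2169 to 2919 and 1077 to 1780 for TAC against running at 2 and 8 weeks. For lncRNA genes it was 0 to 0, 93 to 122 and 109 to 181 for running and TAC at 2 and 8 weeks, and for lists 4 to 10, 21 to 23, 20 to 22 and, between the TAC times, 18 to 24. Genes shared in direction between the TAC times numbered 1925 to 2448, and those shared by running and TAC 0 to 0, or in opposite directions 0 to 3 at 2 weeks and 0 to 0 at 8 weeks. Differences in the mitochondrial share were -0.176 to 3.66, -9.29 to -6.71 and -9.75 to -7.84 percentage points for running and TAC at 2 and 8 weeks. For haemoglobin they were -0.00174 to 0.00324, 0.000767 to 0.0248 and 0.0164 to 0.0213, and for the 10 most abundant genes -0.912 to 2.47, -7.09 to -4.64 and -6.79 to -5.56. The rank correlation of log2 fold changes was 0.569 to 0.694 between the TAC times, -0.141 to 0.0415 between running and TAC at 2 weeks, where it turned positive without running replicate 2 (0.0415) or sedentary replicate 1 (0.0321), and 0.00996 to 0.0941 between running and TAC at 8 weeks. The cause was not tested.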

Other observations

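Annotation classes differed in the direction of their called genes 8 weeks after TAC. Of the class of small and other noncoding genes, 59 of 105 were higher 8 weeks after TAC and 0 lower (edgeR; median log2 fold change 0.69), and 9 of 116 were higher at 2 weeks and 0 lower (median 0.24). The count at 2 weeks was 28, 5 and 5 without TAC replicates 1, 2 and 4, 3 and 4 without sham replicates 2 and 4, 15 by DESeq2, 16 in a fit of all 24 libraries and 43 without normalization factors. Among them was Snora73a, a small nucleolar RNA (0.65 at 8 weeks, edgeR adjusted p = 0.000348), chosen after its value was seen. TEC genes were called lower in 96 of 255 cases and higher in 1 at 8 weeks, and in 26 and 8 of 311 cases at 2 weeks (median -0.09; 11 lower and 58 higher without normalization factors). Pseudogenes were lower in 34 and higher in 10 of 232 cases at 8 weeks and lower in 34 and higher in 15 of 307 at 2 weeks, and protein-coding genes higher in 1933 and lower in 1714 of 12385 cases at 8 weeks. In the test of the difference between the TAC times 0 of 121 small and other noncoding genes were called by edgeR (14 at unadjusted p under 0.05; median 0.46), 1 TEC gene of 322 and 5 lncRNA genes of 712. Values of small RNAs, TEC genes and pseudogenes are uncertain, because short transcripts are recovered unevenly and these genes share reads with copies or with the genes around them.

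Clock transcripts differed between cohorts and groups in level. Arntl, a core activator of the clock, ranged from 4 to 10.9 CPM in sedentary hearts, 0.358 to 2.78 after running, 0.221 to 1.48 in shams of the 2-week cohort, 1.36 to 3.69 in its TAC hearts, 4.25 to 12.1 in shams of the 8-week cohort and 3.24 to 10.4 in its TAC hearts. The clock list was not called for TAC at 2 weeks (4 of 21 higher, 6 lower; 4 and 10 adjusted over the list alone; camera adjusted p = 0.0541) and was called for the difference between TAC at 2 weeks and running (3 higher, 8 lower; 3 and 9 over the list alone; 0.00327, and 0.132 with an estimated correlation). H19 ranged from 6.45 to 9.46 CPM in shams of the 8-week cohort, 2.55 to 4.12 in its TAC hearts, 4.08 to 4.85 in shams of the 2-week cohort and 5.79 to 8.43 in its TAC hearts.

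Other lists separated the sham groups. Genes tied to physiological growth were higher in the 8-week cohort (5 of 22 higher, 1 lower; 10 and 3 adjusted over the list alone; camera adjusted p = 2.38e-06, and 0.156 with an estimated correlation), as were regulators of mitochondrial genes (4 of 20 higher; 8 over the list alone; 0.000543, and 0.184) and heat shock genes (2 of 18 higher, also over the list alone; 0.000609, and 0.65). For heat shock genes sham replicate 1 of the 8-week cohort stood apart, with a mean log2 CPM over the list of 6.56 against at most 5.61 in the other 3 hearts and 4.99 to 5.42 in shams of the 2-week cohort. For erythroid genes 0 of 8 were called over all genes by edgeR and 5 were lower over the list alone (median -0.51; camera adjusted p = 0.000543, and 0.551 with an estimated correlation). Camera called 16 of 36 lists, fry 5, and camera with an estimated correlation 0.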
